A study of Mus musculus with 9 samples.

How the data were processed

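Liver RNA of 9 mouse libraries was sequenced, 3 each from the saline, gefitinib and combined (glycyrrhizic acid with gefitinib) groups, all at 16 days. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a SMARTer kit for messenger RNA. The aligner, the counting tool and whether counting used strand are not given in the sources used here. Genome builds GRCm38 and mm10, 2 names of the same assembly, are named in the submitters' processing notes, and coordinates are given 1-based in that build, as the deposited table lists them. Of the 27945 gene IDs in the table, 27859 are also in GENCODE M21, and 27108 carry the same symbol there.

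The deposited table holds whole-number counts per gene and library, which the authors left unnormalised, per the file headers and the values. It also holds FPKM values that the authors computed per gene and library, per the file headers, and these sum to between 418760 and 455061 per library. All 18 columns of per-sample values matched a library by name. Replicates were not pooled. Pairs of libraries within a group differed well beyond sampling noise, with a chi-square per degree of freedom of 81.8 to 169, so no library was taken as a repeat of another, which does not show that they came from separate animals. Each library was counted as 1 replicate, as labelled.

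Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its defaults, which left 18113 tested genes and 9832 untested, and libraries were scaled by TMM, with factors from 0.905 to 1.14. One quasi-likelihood fit with a mean per group over all 9 libraries gave 6 residual degrees of freedom and the 3 comparisons. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Levels in CPM are mean ± SD over 3 libraries, folds are from the fit, and log2 values for components and lists used a prior count of 2. Folds against a group with 0 counts in every library are lower bounds against a floor of 3 counts per library, and such floors cover counting error only. Overlapping genes and members of gene families may share reads, and are described as uncertain where named.

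Before the data were examined, 50 gene lists were fixed, 33 of pathways and 17 of cell types or other marker groups, with 1122 symbols, of which 1097 are in the table and 1059 were tested. The 48 lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over lists within a comparison. In each comparison 2 lists also passed with an estimated correlation. These were the sinusoidal endothelial list with gefitinib and in the combined group against saline, the CAR and PXR targets with gefitinib, the matrix and immediate early lists in the combined group against gefitinib, and the monocyte-derived macrophage list against saline. Mean log2 scores of lists were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot go below p = 0.1. Named genes followed a rule fixed at the same time. Per comparison it took the 8 largest rises and 8 largest falls among called genes with non-overlapping values, a standard symbol and a mean of at least 1 FPKM in the higher group, up to 3 called members of each list with the smallest adjusted p, and always Egfr and Hsd11b1. Of the genes it took and of the lists called, the text gives a selection.

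The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed. The changed genes were drawn only from those above a minimum mean level, so recovery of low-count genes was not measured. The spread was set to edgeR's own estimates. For gefitinib against saline, with 17451 genes, 3.57% of 1.5-fold, 34.5% of 2-fold and 75.4% of 4-fold changes were recovered, and 6 of 81 calls were false. For combined against gefitinib, with 17444 genes, the shares were 1.79%, 31.0% and 78.9%, with 4 of 77 calls false. For combined against saline, with 17408 genes, they were 1.79%, 41.4% and 86.0%, with 8 of 94 calls false. Fold changes of comparisons with shared libraries were set beside 20 simulations of unchanged groups.

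Alternatives fixed before the data were examined were the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), no filter, a mean of at least 5 FPKM, median-ratio and quantile scaling, a fit of only the 6 libraries compared, a robust prior, array weights, DESeq2 1.42.0, fry, an estimated correlation, and each library left out in turn. A term for muscle transcripts, muscle genes left out, and scaling by library size alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Lists with fewer than 5 tested members were not tested. The result of 1 gene is not reported here.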

Results

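RNA sequencing of mouse liver was deposited as 1 gene table with 9 libraries, 3 each from mice given saline, gefitinib, or glycyrrhizic acid together with gefitinib (the combined group) for 16 days. Gefitinib is an inhibitor of the tyrosine kinase of the epidermal growth factor receptor, and glycyrrhizic acid is a triterpenoid saponin of licorice root. The series was set up around the liver toxicity of gefitinib and its possible relief by glycyrrhizic acid. Doses are not given in the sources used here. Total counts ranged from 56440871 to 60665156 per library. Reads were counted for 27945 genes, of which 18113 had enough counts to be tested. Levels are in CPM, counts scaled to the library total multiplied by its TMM factor. They are given as mean ± SD over the 3 libraries of a group. Folds and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

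The 3 groups were separated along the first principal component of log2 CPM, which held 32.1% of the variance. Saline libraries lay between -70.4 and -54.0 on it, gefitinib libraries between -17.8 and -6.95, and combined libraries between 64.9 and 81.4. The root mean square log2 difference of group means was 0.707 between gefitinib and saline, 0.832 between combined and gefitinib, and 1.03 between combined and saline. Single libraries had a within-group SD of 0.688, but means of 3 libraries vary less, so that SD is no direct yardstick for these differences. Skeletal muscle transcripts differed between libraries in another way. The summed level of 10 muscle transcripts, such as Myh4 and Acta1, was 172 CPM in gefitinib 1 and 151, 119 and 129 CPM in the combined libraries. It was 0.932 and 0.63 CPM in gefitinib 2 and 3, and 0.34, 1.06 and 0.784 CPM in the saline libraries. Hemoglobin transcripts summed to 1881, 1175 and 795 CPM with gefitinib, to 696, 525 and 872 CPM with saline and to 564, 568 and 304 CPM in the combined group.

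**Figure D1:**
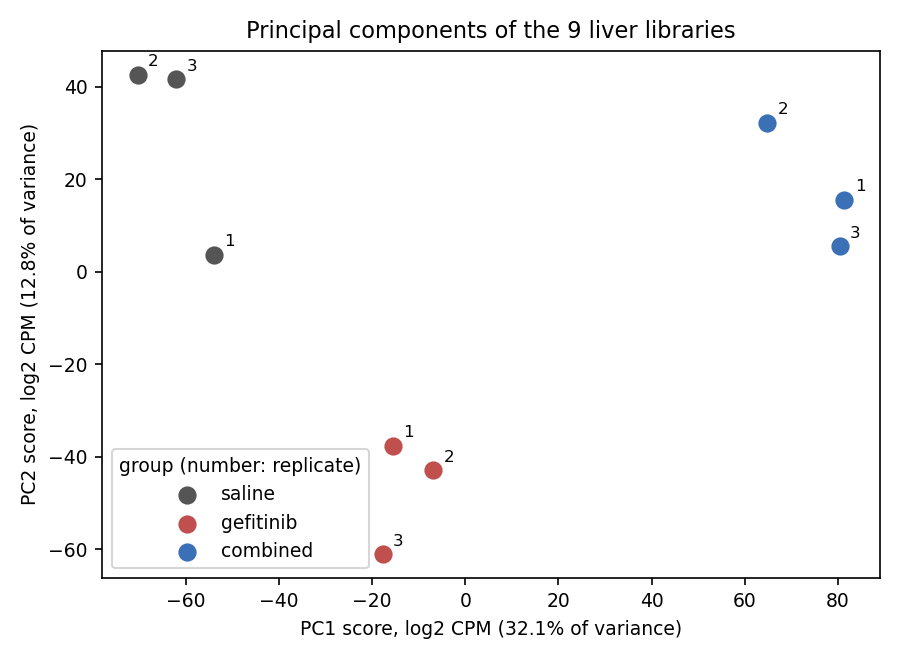
The first 2 principal components of log2 CPM over the tested genes, 1 point per library, coloured by group. The axes give the 32.1% and 12.8% of variance held, and the gefitinib libraries lie between the saline and combined libraries on the first component.

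**Figure D2:**
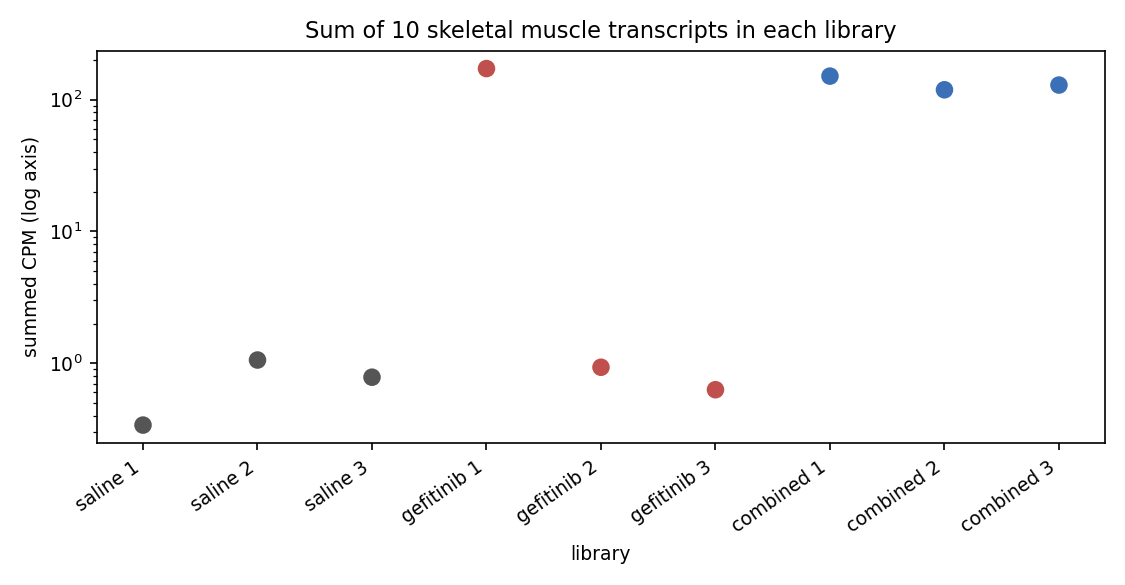
Levels of 10 skeletal muscle transcripts in each of the 9 libraries, in CPM on a log scale. Gefitinib 1 and the 3 combined libraries hold them at sums of 119 to 172 CPM, and the other 5 libraries at sums of at most 1.06 CPM.

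The comparison of gefitinib with saline asked what the drug alone changed in the liver. Genes of the sinusoidal endothelium, the fenestrated lining of the liver capillaries, were lower with gefitinib. Stab2 (ENSMUSG00000035459, chromosome 10, 86841198 to 87008025, GRCm38), a scavenger receptor of these cells, fell 2.26-fold, from 108 ± 15 to 47.9 ± 6.70 CPM (SD, n = 3 per group, adjusted p = 0.011). Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628), a junction protein of endothelial cells, fell 2.93-fold, from 15.8 ± 2.37 to 5.37 ± 0.544 CPM (adjusted p = 0.0101). Tek, the angiopoietin receptor, fell 3.15-fold, and Gpihbp1, which anchors lipoprotein lipase to capillaries, fell 4.26-fold (adjusted p = 0.0101 and 0.0106). Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, fell from 6.92 ± 1.21 to 1.62 ± 0.840 CPM. Of the 16 tested members of the sinusoidal endothelial list, 11 fell, 0 rose and 5 did not pass, and 15 fell adjusted over the list alone. The median log2 fold change of the list was -1.35 (camera, adjusted p = 9.11e-38, and adjusted p = 0.0213 with an estimated correlation). Stellate cell and fibroblast genes had a median of -0.56, with 0 of 16 passing among all genes and 6 lower adjusted over the list alone (camera, adjusted p = 1.48e-05, and adjusted p = 0.301 with an estimated correlation).

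Targets of CAR and PXR, receptors of foreign compounds, were higher with gefitinib. Gsta1, a glutathione transferase, rose 24.5-fold, from 1.75 ± 0.731 to 42.7 ± 33.7 CPM (SD, n = 3 per group, adjusted p = 0.0163). Gstm3, another glutathione transferase, rose 6.51-fold, from 39.9 ± 18.1 to 260.0 ± 124 CPM (adjusted p = 0.0355), and reads of both can be shared with close paralogs. Slco1a4, an organic anion transporter, rose 3.57-fold and Ephx1, the microsomal epoxide hydrolase, rose 1.59-fold (adjusted p = 0.0276 and 0.0482). Among 31 tested CAR and PXR targets, 4 rose, 0 fell and 27 did not pass, and 9 rose adjusted over the list alone. Their median log2 fold change was 0.69 (camera, adjusted p = 6.87e-09, and adjusted p = 0.0204 with an estimated correlation). The 4 that rose were Gsta1, Gsta2, Gstm3 and Slco1a4, and no cytochrome P450 of the list passed. The list of 30 NRF2 targets and glutathione genes, which holds none of these 4, was also higher. In it 0 passed among all genes and 0 adjusted over the list alone (median 0.413, camera, adjusted p = 1.08e-05, and adjusted p = 0.327 with an estimated correlation). Of 45 phase II enzymes, 6 rose and 0 fell, with 10 rising and 1 falling adjusted over the list alone (camera, adjusted p = 4.48e-05, and adjusted p = 0.327 with an estimated correlation). Of 33 other phase I enzymes 1 rose, Ephx1, and 1 fell, Cyp4v3, a fatty acid omega-hydroxylase (adjusted p = 0.0388), with 1 rising and 3 falling adjusted over the list alone, and the list did not pass (median -0.252, camera, adjusted p = 0.0609). Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, rose 5.50-fold, from 45.3 ± 17.0 to 249 ± 117 CPM (adjusted p = 0.0203). Elovl6, which lengthens fatty acids, rose 2.71-fold, Pklr, the liver pyruvate kinase, rose 2.02-fold, and G0s2, an inhibitor of the lipase Pnpla2, fell 4.48-fold.

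Acute phase, interferon response and monocyte-derived macrophage genes were also higher. Hp, haptoglobin, rose 1.78-fold from 3579 ± 449 to 6374 ± 456 CPM (SD, n = 3 per group, adjusted p = 0.0202), Saa2, a serum amyloid A protein whose reads can be shared within its family, rose 5.78-fold, and Lcn2, an iron-siderophore binding protein, rose 6.21-fold. Of 30 acute phase genes, 7 rose, 0 fell and 23 did not pass, and 13 rose adjusted over the list alone (median 0.33, camera, adjusted p = 2e-09, and adjusted p = 0.301 with an estimated correlation). Of 41 interferon response genes, 2 rose and 0 fell, Zbp1 at 3.21-fold and Ifi47 at 2.10-fold, and 12 rose adjusted over the list alone (median 0.42, camera, adjusted p = 4.07e-11, and adjusted p = 0.327 with an estimated correlation). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose 4.78-fold, from 1.56 ± 0.275 to 7.47 ± 2.25 CPM. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), a macrophage elastase, rose 10.1-fold, from 1.28 ± 0.433 to 13 ± 6.15 CPM (adjusted p = 0.0101 for both). Lilr4b, a receptor of myeloid cells whose reads can be shared with its paralog Lilrb4a, rose 6.93-fold, from 3.30 ± 0.765 to 22.9 ± 1.36 CPM (adjusted p = 0.00024). Among 15 genes of monocyte-derived macrophages and dendritic cells, 2 rose and 0 fell, with 3 rising adjusted over the list alone (median 0.92, camera, adjusted p = 4.4e-06, and adjusted p = 0.195 with an estimated correlation), a call lost with quantile normalization. The neutrophil, MHC class II and B and plasma cell lists were higher with 0 members passing among all genes and 8, 0 and 0 rising adjusted over the list alone. Their medians were 3.02 (2.73 with genes absent from saline at their bound), 0.59 and 0.619 (camera, adjusted p = 1.57e-09, 0.0036 and 0.00951, and adjusted p = 0.301, 0.432 and 0.678 with an estimated correlation). The MHC class II call was lost without saline 2 or gefitinib 1, and the B and plasma cell call without saline 2 or with log2(FPKM + 0.1). The inflammatory, Kupffer cell and T and NK cell lists, with 1 of 34, 1 of 16 and 0 of 17 rising, did not pass (camera, adjusted p = 0.0756, 0.193 and 0.422).

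Growth signalling and clock genes moved in both directions. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, fell 4.21-fold, from 10.6 ± 2.43 to 2.51 ± 1.25 CPM, and Fos, an immediate early transcription factor, fell 3.59-fold (SD, n = 3 per group, adjusted p = 0.0377 and 0.0472). Ccnd1, cyclin D1, rose 3.31-fold, from 8.12 ± 2.66 to 26.9 ± 4.77 CPM (adjusted p = 0.0165), and its span overlaps LTO1 on the opposite strand. Of 36 cell cycle genes 2 rose and 0 fell, with 6 rising and 1 falling adjusted over the list alone (median 0.859, camera, adjusted p = 1.45e-08, and adjusted p = 0.327 with an estimated correlation), a call lost with log2(FPKM + 0.1) and with quantile normalization. In the list of EGFR ligands, receptors and MAPK feedback genes, 3 of 31 fell and 1 rose, with 4 falling and 1 rising adjusted over the list alone (median -0.32, camera, adjusted p = 0.0341, and adjusted p = 0.327 with an estimated correlation), a call that was lost without saline 1, without gefitinib 1, with log2(FPKM + 0.1) and with quantile normalization. Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158) itself was at 378 ± 115 CPM with saline and 596 ± 128 CPM with gefitinib, and did not pass (adjusted p = 0.291). Among glucocorticoid response genes, Zbtb16 fell 7.06-fold, from 37.2 ± 16.2 to 5.26 ± 0.869 CPM (adjusted p = 0.00797). Cdkn1a, an inhibitor of cyclin-dependent kinases that is also a p53 target, fell 5.21-fold. In that list 2 of 23 fell and 1 rose, with 5 falling and 1 rising adjusted over the list alone (median -0.30, camera, adjusted p = 1.48e-05, and adjusted p = 0.327 with an estimated correlation). Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), a core activator of the circadian clock, fell 2.88-fold, from 22.8 ± 3.52 to 7.92 ± 1.88 CPM, and Npas2, another gene of the clock list, fell 7.20-fold (adjusted p = 0.0202 and 0.0196). Per3, a clock repressor that shares a strand and part of its span with Camta1, rose 6.05-fold. Of 21 clock genes 2 rose and 3 fell, with 7 and 5 adjusted over the list alone, and the list as a whole did not pass (camera, adjusted p = 0.223).

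In all, 206 genes changed with gefitinib, 99 higher and 107 lower, with 2555 genes at an unadjusted p under 0.05, and with log2(FPKM + 0.1) 99 were higher and 62 lower. Values of the 2 groups did not overlap in 20% of all tested genes, where chance gives 10%. The largest rise among the named genes was that of Gemin4 (ENSMUSG00000049396, chromosome 11, 76210571 to 76217664), a protein of the SMN complex, at 0.0317 ± 0.0293 CPM with saline and 6.80 ± 0.839 CPM with gefitinib (SD, n = 3 per group, adjusted p = 0.000308). Gemin4 overlaps Glod4 on the same strand and Fam57a on the opposite strand, so its reads cannot be assigned with certainty, and a strain difference between the groups was not tested. The largest fall among them was that of Igsf23, of the immunoglobulin superfamily, from 8.61 ± 4.56 to 0.217 ± 0.166 CPM (adjusted p = 0.0101). The number of genes changed was 32 without gefitinib 2, 47 without saline 3, 52 without gefitinib 3, 61 without saline 2, and 75 without gefitinib 1, the 1 library of the group with muscle transcripts. It was 122 and 127 without combined 2 and 3, with 18812 and 18840 genes tested. With a term for the presence of muscle transcripts, added after the data were seen, 73 genes changed. For this comparison the term amounts to leaving gefitinib 1 out, so it is not a separate check. Fos was not called without any 1 of the 9 libraries, and Gsta1 was not called without saline 2 or saline 3. Without gefitinib 2, 34 of the 46 named genes past the threshold were not called, among them Gstm3, Slco1a4, Ephx1, Cyp4v3, Cyp7a1, Elovl6, Pklr, G0s2, Lyve1, Hp, Saa2, Lcn2, Zbp1, Ifi47, Ccnd1, Spry4, Fos, Cdkn1a, Arntl, Npas2 and Per3. The number was 33 without saline 2, 31 without saline 3, 29 without gefitinib 3 and 25 without gefitinib 1. Gpnmb was not called with log2(FPKM + 1), with or without array weights, or with quantile normalization. Stab2, Pecam1, Tek, Gpihbp1, Zbtb16, Mmp12, Lilr4b and Gemin4 passed in each alternative in which they were tested.

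The comparison of the combined group with gefitinib asked what glycyrrhizic acid changed in livers that also received gefitinib. Matrix and monocyte-derived macrophage genes were higher in the combined group. Gpnmb rose 34.0-fold, from 7.47 ± 2.25 to 254 ± 68.1 CPM (SD, n = 3 per group, adjusted p = 0.00013). Mmp12 rose 15-fold to 195 ± 21.4 CPM, and Mmp13, a collagenase, rose 24.0-fold from 0.556 ± 0.227 to 13.4 ± 3.57 CPM (adjusted p = 0.000504 for both). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the alpha 1 chain of type I collagen, rose 7.23-fold, from 7.68 ± 1.61 to 55.6 ± 14.1 CPM (adjusted p = 0.000241). Col1a2 rose 4.55-fold and Col3a1, the chain of type III collagen, rose 5.57-fold (adjusted p = 0.00108 and 0.00148). Of 32 extracellular matrix and fibrosis genes, 18 rose, 0 fell and 14 did not pass, and 22 rose adjusted over the list alone. Their median log2 fold change was 1.37 (camera, adjusted p = 4.97e-26, and adjusted p = 0.0488 with an estimated correlation). In the stellate cell and fibroblast list, which shares the 3 collagen genes, 3 of 16 rose and 1 fell, with 3 and 2 adjusted over the list alone (median 0.528, camera, adjusted p = 0.00112, and adjusted p = 0.219 with an estimated correlation), a call lost with log2(FPKM + 0.1). Among 15 genes of monocyte-derived macrophages and dendritic cells, 5 rose and 0 fell, with Itgax, the integrin CD11c, at 11.1-fold and Cd9, a tetraspanin, at 2.47-fold, and 7 rose adjusted over the list alone (median 1.09, camera, adjusted p = 2.99e-07, and adjusted p = 0.0812 with an estimated correlation). The lysosomal protease Ctss (ENSMUSG00000038642, chromosome 3, 95526786 to 95556403) rose 6.10-fold, from 23.1 ± 5.26 to 141 ± 10.4 CPM, and Lyz2, lysozyme of myeloid cells, rose 6.46-fold (adjusted p = 0.0002 and 0.000963). In the Kupffer cell and macrophage list, which holds Lyz2, 2 of 16 rose and 1 fell, Slc40a1, an iron exporter, also 2 and 1 adjusted over the list alone (median 0.486, camera, adjusted p = 0.0117, and adjusted p = 0.511 with an estimated correlation). That call was lost without gefitinib 3, without combined 3, with log2(FPKM + 0.1) and with quantile normalization. The 3 combined libraries in which these genes were higher also held muscle transcripts, as did gefitinib 1.

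Immediate early, p53 target and glucocorticoid response genes were higher as well. Klf6 (ENSMUSG00000000078, chromosome 13, 5861482 to 5870394), a zinc finger transcription factor, rose 5.56-fold, from 10.6 ± 0.590 to 59.1 ± 7.22 CPM, and Atf3, a stress-responsive transcription factor, rose 11.6-fold (SD, n = 3 per group, adjusted p = 0.000143 and 0.0002). Fos rose 11.4-fold (adjusted p = 0.000866). Of 17 immediate early genes that tissue handling is known to raise, 9 rose and 0 fell, and 13 rose adjusted over the list alone (median 2.11, camera, adjusted p = 1.23e-21, and adjusted p = 0.0488 with an estimated correlation). Cdkn1a rose 14.9-fold, from 8.89 ± 0.851 to 132 ± 40.6 CPM, and Trp53inp1, a p53 target, rose 5.44-fold. Of 26 p53 targets, 9 rose and 0 fell, with 15 rising adjusted over the list alone (median 0.88, camera, adjusted p = 4.34e-10, and adjusted p = 0.0558 with an estimated correlation). Zbtb16 rose 5.90-fold and Sgk1, a kinase induced by glucocorticoids, rose 3.63-fold. Of 23 glucocorticoid response genes, 11 rose and 0 fell, with 15 rising and 1 falling adjusted over the list alone (median 1.51, camera, adjusted p = 1.36e-13, and adjusted p = 0.111 with an estimated correlation). Dusp6, a phosphatase that acts on ERK, rose 4.12-fold, and 10 of 31 EGFR and MAPK feedback genes rose while 1 fell, with 11 and 2 adjusted over the list alone (median 0.55, camera, adjusted p = 5.66e-07, and adjusted p = 0.0558 with an estimated correlation). The immediate early list shares Fos, Jun, Junb, Egr1 and Ier2 with the EGFR and MAPK feedback list, and Dusp1 and Zfp36 with the glucocorticoid list. The glucocorticoid and p53 lists share Cdkn1a and Gadd45b, so the rises of these lists are not independent of each other. Il1rn, the interleukin 1 receptor antagonist, rose 6.40-fold. Of 34 inflammatory cytokine and chemokine genes, 11 rose and 1 fell, with 16 and 1 adjusted over the list alone (median 1.12, camera, adjusted p = 4.96e-10, and adjusted p = 0.0558 with an estimated correlation). Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193243561), which regenerates active glucocorticoid, was at 492 ± 67.0 and 398 ± 68.0 CPM and did not pass (adjusted p = 0.274).

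Targets of the oxidative stress regulator NRF2 were higher. Srxn1, sulfiredoxin, rose 8.62-fold, from 43.5 ± 4.82 to 375 ± 258 CPM, and Pgd, an NADPH-producing enzyme of the pentose phosphate pathway, rose 3.66-fold, from 29.2 ± 0.164 to 107 ± 42.5 CPM (SD, n = 3 per group, adjusted p = 0.00172 and 0.00147). Gstm3, which is in the CAR and PXR and the phase II lists but not in the NRF2 list, rose 6.02-fold to 1565 ± 646 CPM (adjusted p = 0.0104). Of 30 NRF2 targets and glutathione genes, 12 rose and 0 fell, and 17 rose adjusted over the list alone (median 0.51, camera, adjusted p = 2.1e-09, and adjusted p = 0.202 with an estimated correlation).

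Phase I, fatty acid, respiratory and bile acid genes were lower, while other lists of drug metabolism were not. Ces3b (ENSMUSG00000062181, chromosome 8, 105083753 to 105093929), a carboxylesterase, fell 3.70-fold, from 605 ± 53.1 to 163 ± 39.1 CPM, and Ephx2, the soluble epoxide hydrolase, fell 1.74-fold (SD, n = 3 per group, adjusted p = 0.000941 and 0.0145). Of 33 other phase I enzymes, 6 fell and 0 rose, and 9 fell adjusted over the list alone (median -0.39, camera, adjusted p = 4.41e-07, and adjusted p = 0.219 with an estimated correlation). Of 31 CAR and PXR targets 2 rose and 2 fell, with 4 and 6 adjusted over the list alone, and of 45 phase II enzymes 4 rose and 6 fell, with 9 and 12 (camera, adjusted p = 0.907 and 0.336). Of 10 AhR targets 4 rose and 0 fell, also 4 adjusted over the list alone (median 0.441, camera, adjusted p = 0.00638, and adjusted p = 0.135 with an estimated correlation), a call lost with log2(FPKM + 0.1). Cyp4a10, a fatty acid omega-hydroxylase, fell 4.81-fold, from 761 ± 296 to 158 ± 59.9 CPM (adjusted p = 0.0144), whereas Ucp2, a mitochondrial carrier, rose 2.05-fold. Of 43 PPAR alpha targets and fatty acid oxidation genes, 13 fell and 2 rose, with 25 and 3 adjusted over the list alone (median -0.44, camera, adjusted p = 4.51e-06, and adjusted p = 0.359 with an estimated correlation). Sdhb, a subunit of respiratory complex II, fell 1.42-fold. Of 38 oxidative phosphorylation genes, 4 fell and 0 rose, and 22 fell adjusted over the list alone (median -0.30, camera, adjusted p = 5.66e-07, and adjusted p = 0.28 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, fell 2.21-fold and Slc10a1, the sodium-dependent bile acid importer, fell 2.15-fold, whereas Abcc4, a basolateral exporter, rose 10.1-fold. Of 26 bile acid genes 6 fell and 1 rose, with 8 and 1 adjusted over the list alone (median -0.36, camera, adjusted p = 0.00105, and adjusted p = 0.202 with an estimated correlation). Hepatocyte markers were lower in the same libraries, with 4 of 14 falling and 1 rising, and 5 and 2 adjusted over the list alone (median -0.218, camera, adjusted p = 0.0172, and adjusted p = 0.413 with an estimated correlation), a direction that turned with quantile normalization and a call lost without combined 1. Of 14 periportal hepatocyte markers 3 fell and 0 rose, also 3 adjusted over the list alone (median -0.306, camera, adjusted p = 0.00459, and adjusted p = 0.202 with an estimated correlation), a call lost with quantile normalization. Sinusoidal endothelial genes were lower again, with 6 of 16 falling and 0 rising, and 10 falling adjusted over the list alone (median -0.70, camera, adjusted p = 3.1e-06, and adjusted p = 0.202 with an estimated correlation). The immediate early genes stood higher by a median of 2.11 in the same combined libraries.

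In all, 1644 genes changed between the combined group and gefitinib, 899 higher and 745 lower, with 4403 at an unadjusted p under 0.05. Values of the 2 groups did not overlap in 31.2% of all tested genes, where chance gives 10%. The 8 largest rises among the named genes were those of Igsf23, Gpnmb, Elovl7, Mmp13, Cbr3, Sprr1a, H2-M2 and Mmp12, in that order, and the 8 largest falls those of Dbp, Onecut1, Clec2h, Cib3, Hamp2, Cyp46a1, Nrep and Per3. Igsf23 rose from 0.217 ± 0.166 to 27.1 ± 7.91 CPM (SD, n = 3 per group, adjusted p = 0.000504). With library size alone as the scaling, 1513 genes were higher and 380 lower. Limma on the deposited FPKM values, with 10618 genes tested, gave 1598 higher and 412 lower. After quantile normalization of those values 756 were higher and 846 lower. Library size alone and the deposited FPKM values moved the median log2 fold change of all genes to 0.11 and 0.12. The changes above are therefore relative to a median near 0, and the balance of higher and lower genes depends on the processing. All 3 combined libraries and 1 of 3 gefitinib libraries held muscle transcripts, and the muscle list had a median of 1.31 with 0 of 11 members passing (camera, adjusted p = 0.00169, and adjusted p = 0.415 with an estimated correlation). The number of genes changed was 751 without gefitinib 1, 859 without gefitinib 3, 867 without combined 1 and 901 without combined 3. With the term for muscle transcripts 516 genes changed. Itgax, Sdhb, Cyp4a10, Ephx2, Elovl7, Cbr3, Sprr1a, H2-M2, Onecut1, Cib3 and Per3 were not called with that term. Onecut1 and Cib3 were not called without any 1 of the 6 libraries compared, Dbp, Cyp4a10 and Per3 without combined 1 or 3, Ephx2 without gefitinib 1 or combined 3, and Cyp46a1 without gefitinib 1 or combined 2.

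**Figure D3:**
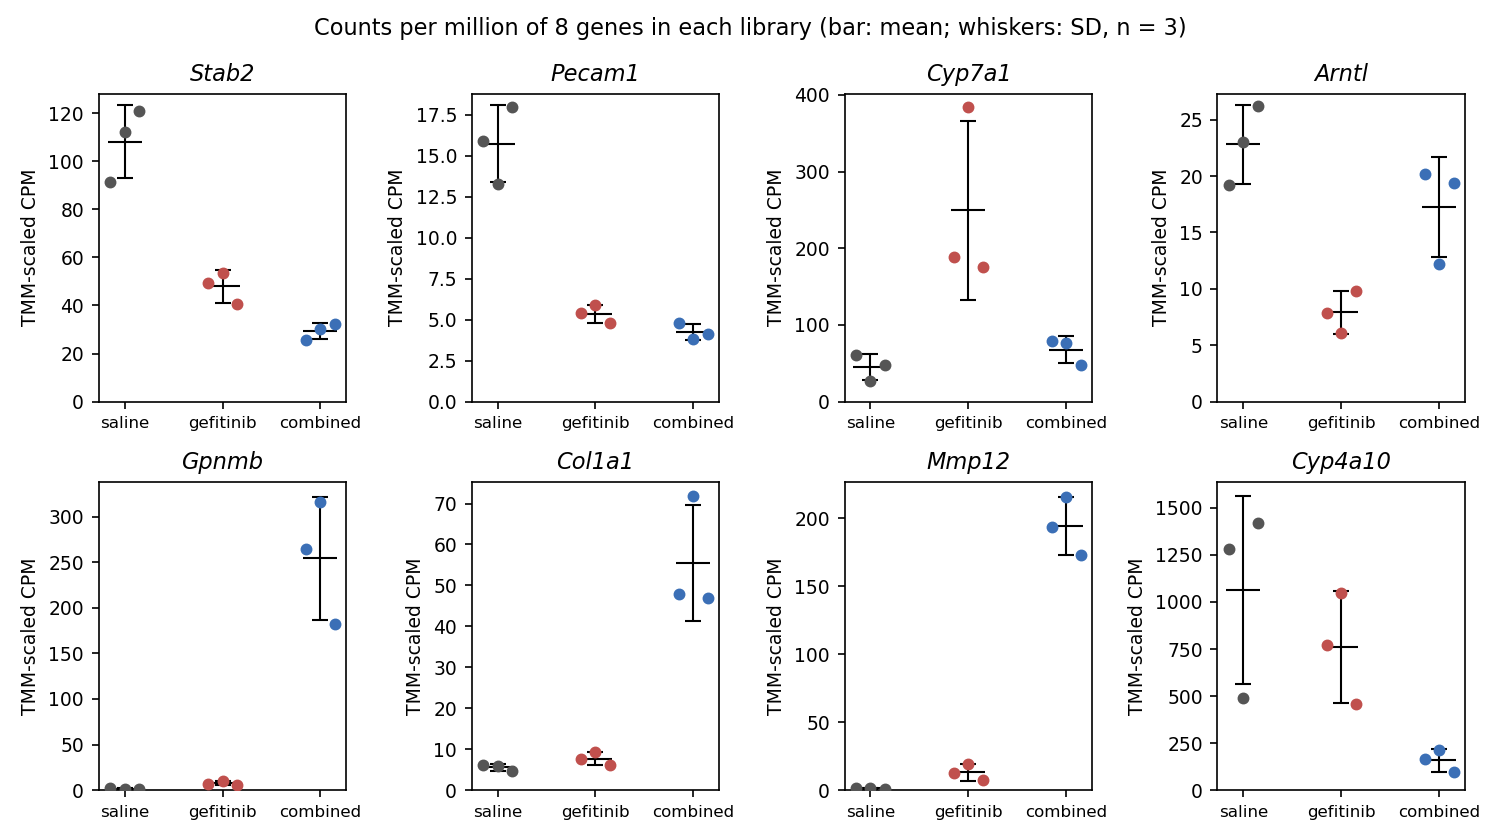
Levels of 8 genes in CPM on a linear scale, 1 point per library, with the group mean and SD of 3 libraries. Stab2 and Pecam1 fell with gefitinib, Cyp7a1 rose and Arntl fell, and Gpnmb, Col1a1 and Mmp12 were highest and Cyp4a10 lowest in the combined group.

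The comparison of the combined group with saline asked what difference from untreated liver was left when both compounds were given. Monocyte-derived macrophage and matrix genes were higher than with saline. Gpnmb rose 163-fold, from 1.56 ± 0.275 to 254 ± 68.1 CPM (SD, n = 3 per group, adjusted p = 5.89e-06), Mmp12 rose 152-fold and Col1a1 rose 9.92-fold (adjusted p = 2.32e-05 and 4.67e-05). Cd68, a lysosomal marker of macrophages, rose 7.26-fold, from 7.49 ± 0.210 to 54.3 ± 7.05 CPM (adjusted p = 5.05e-05). In its list, of Kupffer cells and macrophages, 5 of 16 rose and 2 fell, with 8 and 3 adjusted over the list alone (median 0.596, camera, adjusted p = 0.00445, and adjusted p = 0.478 with an estimated correlation), a call lost without saline 2, with log2(FPKM + 0.1) and with quantile normalization. Of 15 genes of monocyte-derived macrophages and dendritic cells, 7 rose and 0 fell, with 9 rising and 1 falling adjusted over the list alone (median 1.68, camera, adjusted p = 2e-10, and adjusted p = 0.0495 with an estimated correlation). Of 32 matrix genes, 14 rose and 0 fell, and 15 rose adjusted over the list alone (median 0.79, camera, adjusted p = 4.56e-13, and adjusted p = 0.0885 with an estimated correlation). Sinusoidal endothelial genes were lower throughout the list, with 16 of 16 falling, and 16 adjusted over the list alone (median -2.00, camera, adjusted p = 8.2e-30, and adjusted p = 0.0495 with an estimated correlation). Stab2 fell 3.68-fold to 29.4 ± 3.22 CPM, and Fcgr2b, the inhibitory Fc receptor of these cells, fell 4.35-fold, from 49.8 ± 6.18 to 11.4 ± 2.23 CPM (adjusted p = 9.69e-05 and 8.35e-05). Cxcl12, a chemokine, fell 2.20-fold while Tlr2, a receptor of bacterial lipoproteins, rose 6.07-fold. Of 34 inflammatory genes, 14 rose and 2 fell, with 17 and 3 adjusted over the list alone (median 1.37, camera, adjusted p = 5.25e-10, and adjusted p = 0.0706 with an estimated correlation).

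Cell cycle, NRF2 target and interferon response genes were higher than with saline. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925) rose 7.80-fold, from 8.12 ± 2.66 to 63.4 ± 13.9 CPM, and Mcm6, a subunit of the replicative helicase, rose 3.02-fold (SD, n = 3 per group, adjusted p = 0.00014 and 0.000643). Of 36 cell cycle genes, 22 rose and 1 fell, with 31 and 1 adjusted over the list alone (median 1.78, camera, adjusted p = 4.56e-13, and adjusted p = 0.18 with an estimated correlation). The 1 that fell was Tk1, thymidine kinase 1, at 2.99-fold, and its span overlaps Afmid on the opposite strand. Gsta1 rose 102-fold, from 1.75 ± 0.731 to 177 ± 68.7 CPM, Gstm3 rose 39.2-fold and Nqo1, a quinone reductase, rose 5.97-fold (adjusted p = 0.000335, 0.000287 and 0.000663). Of 30 NRF2 targets and glutathione genes, 19 rose and 1 fell, with 21 and 1 adjusted over the list alone (median 0.91, camera, adjusted p = 1.8e-13, and adjusted p = 0.114 with an estimated correlation). Gsta1 and Gstm3 are not in that list but in the phase II and the CAR and PXR lists. Of 45 phase II enzymes, 11 rose and 7 fell, with 11 and 8 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.163). The 31 CAR and PXR targets were higher, with 10 rising and 4 falling, and 11 and 5 adjusted over the list alone (median 0.35, camera, adjusted p = 0.00113, and adjusted p = 0.0706 with an estimated correlation). That call was lost with log2(FPKM + 0.1). Usp18, which removes ISG15 from proteins, rose 4.94-fold, and Irf7, an interferon regulator that overlaps Phrf1 on the opposite strand, rose 6.06-fold. Of 41 interferon response genes, 21 rose and 1 fell, with 28 and 1 adjusted over the list alone (median 1.00, camera, adjusted p = 4.56e-13, and adjusted p = 0.18 with an estimated correlation). Klf6 rose 7.96-fold and Atf3 rose 26.1-fold, and 9 of the 17 immediate early genes rose, also 9 adjusted over the list alone, while 0 fell (median 1.23, camera, adjusted p = 6.96e-12, and adjusted p = 0.0706 with an estimated correlation).

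Male-biased and oxidative metabolism genes were lower than with saline. Mup3, a major urinary protein, fell 3.72-fold, from 7067 ± 468 to 1899 ± 681 CPM, and Mup21 fell 21.4-fold, from 319 ± 152 to 14.9 ± 3.47 CPM (SD, n = 3 per group, adjusted p = 0.00134 and 0.0016). Reads of this family can be shared among its near-identical members. Of 25 male-biased liver genes, 12 fell and 0 rose, and 21 fell adjusted over the list alone (median -1.34, camera, adjusted p = 2.01e-10, and adjusted p = 0.0885 with an estimated correlation). Cyp4a10 fell 6.73-fold, and 22 of 43 PPAR alpha targets fell while 2 rose, with 30 and 2 adjusted over the list alone (median -0.55, camera, adjusted p = 3.79e-07, and adjusted p = 0.333 with an estimated correlation). Of 33 other phase I enzymes 18 fell and 1 rose, with 20 and 3 adjusted over the list alone (median -0.72, camera, adjusted p = 4.32e-08, and adjusted p = 0.18 with an estimated correlation). Of 14 hepatocyte markers 5 fell and 1 rose, with 6 and 1 adjusted over the list alone (median -0.225, camera, adjusted p = 0.0102, and adjusted p = 0.359 with an estimated correlation), a direction that turned with quantile normalization. Ndufb9, a subunit of respiratory complex I, fell 1.71-fold, and 19 of 38 oxidative phosphorylation genes fell while 0 rose, with 25 falling and 1 rising adjusted over the list alone (median -0.32, camera, adjusted p = 1.5e-06, and adjusted p = 0.305 with an estimated correlation). Hsd11b1 fell 1.55-fold, from 618 ± 66.1 to 398 ± 68.0 CPM (adjusted p = 0.0222), and Egfr, at 469 ± 122 CPM, did not pass (adjusted p = 0.463).

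In all, 3205 genes changed between the combined group and saline, 1698 higher and 1507 lower, with 5758 at an unadjusted p under 0.05. Values of the 2 groups did not overlap in 37.3% of all tested genes, where chance gives 10%. With library size alone as the scaling, 2980 genes were higher and 805 lower. Limma on the deposited FPKM values, with 10618 genes tested, gave 2711 higher and 695 lower. After quantile normalization of those values 1277 were higher and 1475 lower, and edgeR at a mean of at least 5 FPKM gave 775 and 806. Library size alone and the deposited FPKM values moved the median of all genes to 0.13 and 0.16 on the log2 scale. The 8 largest falls among the named genes were those of Mup6, Mup7, Mup21, Mup1, Cxcl13, Hamp2, Krt23 and Cyp46a1, in that order. Skeletal muscle transcripts were among the largest rises. Myh1, a fast myosin heavy chain, was at 0 counts in each saline library and at 12.9 ± 3.73 CPM in the combined group (SD, n = 3), at least 231-fold higher against a floor of 3 counts per library. Ckm, muscle creatine kinase, was at least 184-fold higher by the same floor. Of 11 muscle genes 10 rose, also 10 adjusted over the list alone, with a median log2 fold change of 9.27, or 7.52 with such genes at their bound (camera, adjusted p = 2.06e-05, and adjusted p = 0.359 with an estimated correlation). The number of genes changed was 2065 without combined 1 and 2136 without saline 2. Myh1 and Ckm were not called without any 1 of the 6 libraries compared, and Hsd11b1 was not called without saline 2, saline 3 or combined 1. Krt23 was not called without saline 1, saline 2 or combined 1, Cxcl13 without saline 3 or combined 1, Mup6 without saline 1 and Mup1 without combined 3. With the term for muscle transcripts 566 genes changed, while the folds of the 3205 genes had a median ratio of 1.1 to those without it and 3198 kept their sign. Myh1, Ckm, Cyp4a10, Nqo1, Hsd11b1, Mup1, Mup6, Mup7, Cxcl13 and Krt23 were not called with it.

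**Figure D4:**
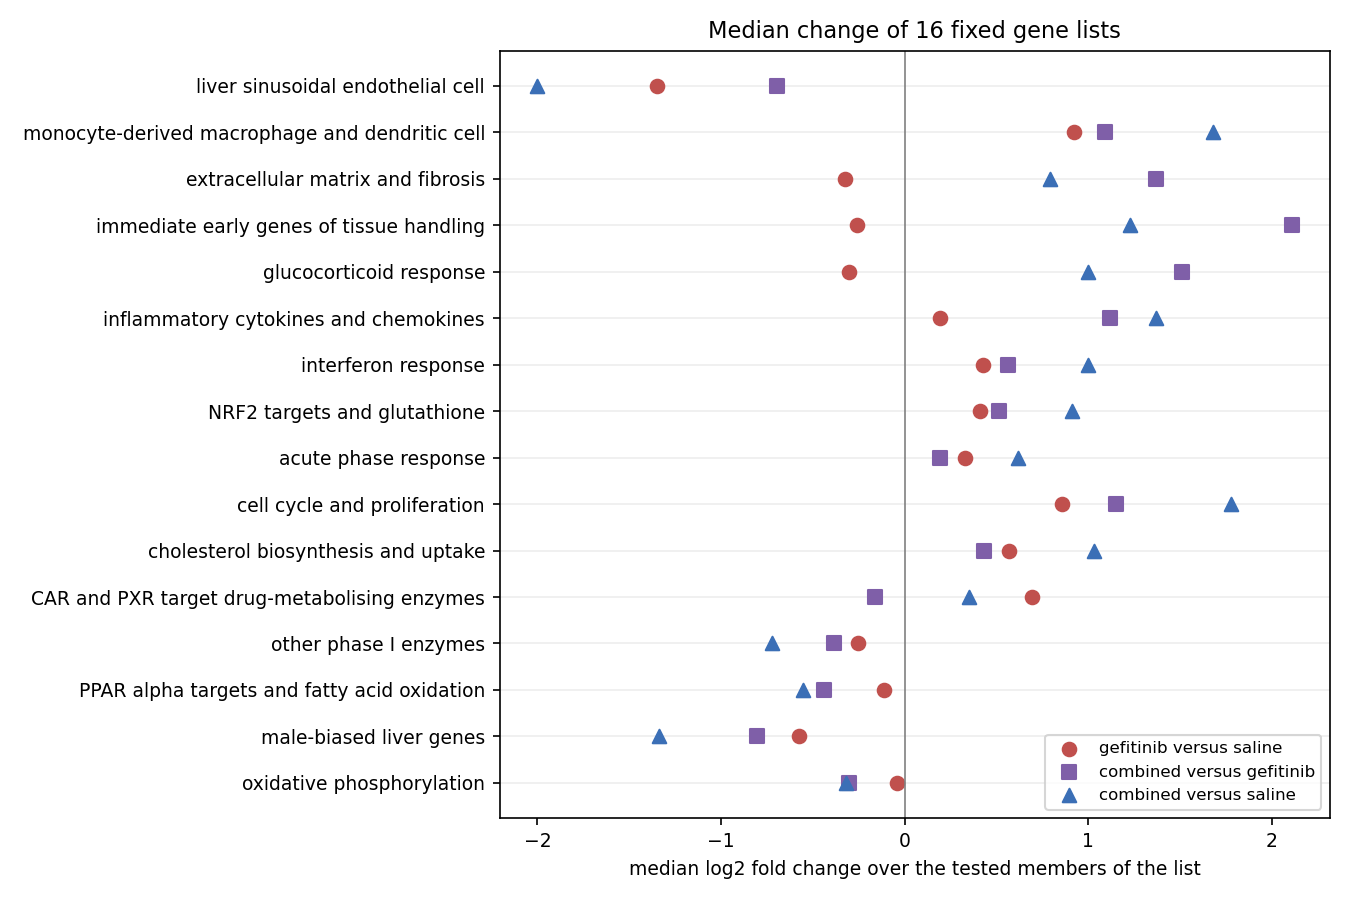
Median log2 fold change of 16 fixed gene lists in each of the 3 comparisons. Sinusoidal endothelial genes lie below 0 in each comparison, at -1.35, -0.70 and -2.00, and matrix genes at 1.37 in the combined group against gefitinib.

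Whether glycyrrhizic acid turned back the changes seen with gefitinib was asked for the 206 genes called against saline. Of these, 41 were called in the opposite direction between the combined group and gefitinib, 47 were called further in the same direction and 118 were not called. The 41 comprised 13 genes that rose and 28 that fell with gefitinib. Of the 41, 35 were not called against saline in the combined group, which does not show a return to the saline level. Zbtb16 and Arntl, which fell with gefitinib, and Cyp7a1 and Per3, which rose, were among these 35. All clock-list genes called with gefitinib, Arntl, Npas2, Nfil3, Per3 and Tspan4, were among them too. For these genes a different time of collection of the gefitinib libraries cannot be told apart from a turn by glycyrrhizic acid. Collection times are not given in the sources used here. Cdkn1a and Fos fell with gefitinib but were called above saline in the combined group, at log2 fold changes of 1.513 and 1.671 (edgeR, adjusted p = 0.0163 and 0.00931). Stab2, Tek, Gpnmb, Mmp12, Lcn2, Ccnd1 and Gsta1 were among the 47. Between combined and gefitinib, Per3 was not called without gefitinib 1, combined 1 or combined 3, Stab2 without gefitinib 1, gefitinib 2 or combined 1, and Tek without gefitinib 1, gefitinib 3, combined 1 or combined 3. Tek was also not called with library size alone as the scaling or in a fit of the 6 libraries, and Per3, Stab2, Tek and Lcn2 were not called with the term for muscle transcripts. Against saline, 152 of the 206 were called in the same direction in the combined group and 4 in the opposite direction. By direction alone, 42.7% ± 2.19 of the 206 moved opposite (SD over the 3 combined libraries), and the median ratio of the log2 change against saline, combined over gefitinib, was 1.17 ± 0.0213. When 2 gefitinib libraries selected the genes and the remaining library measured the change, 26.7%, 31.2% and 25% of 75, 32 and 52 genes moved opposite. The ratios were then 1.499, 1.262 and 1.519, and the 1.17 above comes from genes selected by the same gefitinib libraries that form its denominator.

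The comparisons share libraries, which alone correlates their fold changes. Across the 18113 genes, which are not independent replicates, the fold changes of gefitinib against saline and of combined against gefitinib had r = -0.137 and a covariance of -0.119. With unchanged groups, 20 simulations gave r = -0.502 and a covariance of -0.236, a difference in covariance of 0.117. For gefitinib against saline and combined against saline, r was 0.649 where unchanged groups gave 0.501, and the covariance was 0.739 against 0.236, a difference of 0.503. Independent lists would share 4.07 genes that rose and then fell, 5.31 that fell and then rose, 4.91 that rose further and 4.4 that fell further, where 13, 28, 36 and 11 were shared. They would share 9.28 genes higher and 8.9 lower against saline with both treatments, where 81 and 71 were shared. Sharing the gefitinib libraries alone would lower the counts that rose or fell further, since unchanged groups gave the same sign in 33.4% of genes. Part of the other excesses may come from the shared libraries.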

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

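The muscle term, the omission of muscle genes and scaling by library size alone were chosen after seeing the data. All 1644 genes called between the combined group and gefitinib kept their sign with the muscle term, and 445 were still called. With that term the comparison becomes the combined group against gefitinib 1. Values of the 2 groups did not overlap for 1639 of the 1644, so the kept signs could be foreseen and add no support. Named genes past the threshold passed in each alternative in 9 of 46, 62 of 124 and 68 of 136 cases (gefitinib against saline, combined against gefitinib, combined against saline), and 307, 313 and 216 of their values fell short of the threshold in the same direction. With the muscle term, Myh4, Tnnt3 and Mylpf in the combined group against saline turned to -5.63, -4.25 and -0.28 on the log2 scale and were not called (adjusted p = 0.304, 0.346 and 0.892). That term is estimated from gefitinib 1 alone. The hepatocyte list turned direction with quantile normalization, with adjusted p = 0.695 against gefitinib and 0.716 against saline, and the cause was not tested.

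The 206 genes of gefitinib against saline became 82 without a filter, 99 at a mean of at least 5 FPKM, where fewer genes were tested, 866 with DESeq2 and 73 with the muscle term. The 1644 of combined against gefitinib became 1092, 920, 2750 and 516, and the 3205 of combined against saline became 1581 at 5 FPKM and 566 with the muscle term. In simulated data, whose spread was set to edgeR's estimates, DESeq2 made 36 false calls of 150, 41 of 163 and 54 of 164. Muscle genes left out gave 208, 1672 and 3202, and library size alone 171, 1893 and 3785. Leaving out 1 library gave 32 to 171, 751 to 1497 and 2065 to 2967 genes, lowest without gefitinib 2, gefitinib 1 and combined 1. Without gefitinib 1, 62, 698 and 2833 of the called genes were called again. Gene lists called numbered 18, 34 and 29, and with 1 library left out 18 to 22, 30 to 36 and 28 to 32. With an estimated correlation 2, 2 and 2 lists passed, and with fry 2, 27 and 30. The clock and apoptosis lists between combined and gefitinib were not called without gefitinib 1, gefitinib 2, combined 1 or combined 3.

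The share of the 206 genes moving opposite, 42.72%, was 40.37% with log2(FPKM + 0.1), 39.02% without a filter and 46.25% with quantile normalization. It was 26.67%, 31.25% and 25% when genes were selected without gefitinib 1, 2 or 3 and measured against it, and 31.25% to 46.46% with 1 library left out. Replicate numbers did not pair the libraries, since the 9 same-number correlations of deviations from group means lay between -0.0756 and 0.0716. With the replicate number as a block (replicate block), 82, 1028 and 2496 genes changed and 37.8% of the genes moved opposite. At these depths and n = 3, simulated 1.5-fold changes were recovered in 1.79% to 3.57% of cases with edgeR and in 14.29% to 28.57% with DESeq2, and depth was not varied.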

Other observations

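The tests of explanations below were chosen after the results were seen, except the splits of the libraries. The values for the muscle term were set beforehand, but the term itself was added after the data were seen. Neutrophil genes were higher in both treated groups. Of 13 tested, 0 passed among all genes with gefitinib and 8 rose adjusted over the list alone, with a median log2 fold change of 3.02, or 2.73 with genes absent from saline at their bound (camera, adjusted p = 1.57e-09, and adjusted p = 0.301 with an estimated correlation). In the combined group against saline 9 rose and 0 fell, with 10 rising adjusted over the list alone and a median of 4.63, or 4.31 at the bound (camera, adjusted p = 5.27e-06, and adjusted p = 0.305 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, rose 2.78-fold, and Mmp8, a neutrophil collagenase with 0 counts in each saline library, was at least 19.8-fold higher. Genes of cholesterol synthesis and uptake rose in the combined group against saline, 16 of 25 with 0 falling, and 17 adjusted over the list alone (median 1.03, camera, adjusted p = 7.22e-09, and adjusted p = 0.359 with an estimated correlation). Dhcr7, the last enzyme of the synthesis pathway, rose 3.37-fold (edgeR quasi-likelihood test, adjusted p = 0.000824). The list was also higher with gefitinib against saline, with 0 passing among all genes and 4 rising adjusted over the list alone (median 0.566, camera, adjusted p = 4.09e-09, and adjusted p = 0.432 with an estimated correlation). Between combined and gefitinib 1 of 25 rose and 0 fell (median 0.43, camera, adjusted p = 0.0077, and adjusted p = 0.605 with an estimated correlation).

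Of 8 genes of MHC class II antigen presentation, 4 rose and 0 fell in the combined group against saline, also 4 adjusted over the list alone (median 1.52, camera, adjusted p = 6.73e-08, and adjusted p = 0.137 with an estimated correlation). Cd74, the invariant chain, rose 3.13-fold, and H2-Ab1 rose 4.09-fold. With the muscle term Csf3r, Mmp8, Dhcr7, Cd74 and H2-Ab1 were not called against saline. Erythroid genes were lower in the combined group than with gefitinib, with 5 of 11 falling and 1 rising, and 6 and 1 adjusted over the list alone (median -1.19, camera, adjusted p = 0.00272, and adjusted p = 0.217 with an estimated correlation). Against saline the list was higher with gefitinib, with 0 passing among all genes and 5 rising adjusted over the list alone (median 0.774, camera, adjusted p = 0.00154, and adjusted p = 0.301 with an estimated correlation), a call lost with log2(FPKM + 0.1) or quantile normalization, and did not pass in the combined group (adjusted p = 0.696). Hba-a1, an alpha globin whose reads can be shared with its copy, fell 2.62-fold, from 480 ± 168 to 183 ± 41.7 CPM (SD, n = 3 per group). In the 38 genes of cytosolic ribosomal proteins, 0 rose or fell between combined and gefitinib, also 0 adjusted over the list alone, and the median was 0.30 (camera, adjusted p = 8.89e-05, and adjusted p = 0.511 with an estimated correlation). Gemin4 counts were 0, 3 and 2 in the saline libraries and 429, 396 and 348 in the gefitinib libraries. The combined group was also higher than saline in Gemin4, by a log2 fold change of 7.761 (edgeR, adjusted p = 4.01e-05). Against gefitinib it was at 0.080 and did not pass (edgeR, adjusted p = 0.917). With gefitinib, Chil3, a chitinase-like protein of macrophages, was at 0.822 ± 0.347 CPM (SD, n = 3), and with saline at 0.0238 ± 0.0413 CPM (edgeR, adjusted p = 0.0497). It was not called without any 1 of the libraries other than saline 1. The call was also lost with the replicate block, without a filter, in a fit of only the libraries compared and with the muscle term.

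Skeletal muscle transcripts stood high in gefitinib 1 and the 3 combined libraries. An effect of gefitinib on muscle genes is argued against by gefitinib 2 and 3, whose highest sum was 0.932 CPM, within the saline range. Of 16 other muscle genes, 15 were higher in gefitinib 1 and each combined library than in each saline library, Neb being the exception, which is consistent with skeletal muscle tissue or RNA in those libraries, and Myh4, of the fixed list, was at 43.2 ± 9.06 CPM in the combined group (SD, n = 3). The highest of the 4 sums was 1.45 times the lowest, and whether the RNA came from a shared pool or from tissue taken with each liver cannot be told apart, since the sources used here do not say how the livers were taken. An effect in the combined group alone was not tested.

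The combined group lay farther from saline than the gefitinib group did. Hepatocyte markers were lower in the combined group than with gefitinib (median -0.218), but a lower share of hepatocytes would raise the other cell types alike, and is argued against as the whole source by the medians of the sinusoidal endothelial list, -0.697, and of monocyte-derived macrophages, 1.09. Whether the difference follows muscle content cannot be told apart from treatment. With the muscle term the median fold ratio of the 1644 called genes was 1.07 and 516 genes were called, values set beforehand as arguing against it. However, all 3 combined libraries and no saline library hold muscle transcripts, so the term rests on gefitinib 1 alone. The comparison then becomes the combined group against gefitinib 1, so a ratio near 1 could be foreseen and decides nothing. Exchanged labels of the 2 treated groups cannot be told apart either, since the root mean square log2 difference from saline was 1.03 for the combined group and 0.707 for gefitinib, and nothing in the table records which livers received glycyrrhizic acid; an effect of the combined treatment stays among the open explanations.

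Clock genes differed in the gefitinib group. The mean of the Dbp arm minus that of the Arntl arm was 2.46 ± 0.573 log2 CPM with gefitinib, -0.309 ± 0.465 with saline and -0.102 ± 1.12 in the combined group (SD, n = 3), where combined 2, at 1.18, stood above combined 1 and 3, at -0.592 and -0.894, and below gefitinib 3, at 1.83. An exact two-sided permutation test of the 3 gefitinib against the 6 other libraries gave p = 0.0119, the smallest its 84 arrangements allow, but the genes and the grouping were chosen after the shift was seen, so it adds no support, and another clock phase cannot be told apart from other effects on these genes. The difference was 2.66, and a different time of collection could give it as well as a drug effect, and these cannot be told apart because collection times are not given in the sources used here.

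There are 10 splits of the 6 libraries of a comparison, too few for a share under 0.05. The real split gave 206 genes for gefitinib against saline, 1644 for combined against gefitinib and 3205 for combined against saline, and the highest other split gave 1, 1 and 1, so 1 of 10 splits gave as many in each.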
